A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

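Total RNA from S. cerevisiae in mid-log growth in rich medium was hybridized as biotin-labelled cRNA to one-colour oligonucleotide arrays, 2 of a wild-type strain and 2 of a strain with 8 H3 lysines changed to glycine. Signals were made with MAS5 per the submitters' processing notes. Its version and scaling target are not given in the sources used here. The deposited values are intensity on a linear scale, from 0 to 7497 with 79 zeros, and their trimmed mean was close to equal on all arrays (125.1 on each), so no further normalization was applied. Of 9335 probe sets, the platform's table paired 6504 with 1 gene, 328 with several and 2503 with none. Symbols were updated through the gene identifiers to the current reference gene table. No coordinates were used, since the array's genome build is not named. A probe set with several genes was assigned to none of them.

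Genes were tested on log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), mutant minus wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tested probe sets had 1 gene and a mean log2 signal at or above the 25th percentile of such probe sets, a signal of 25.1, and for a gene with several probe sets the brightest was kept, which left 4476 genes. The fit had 2 residual and 7.03 prior degrees of freedom, and the median standard error of a log2 fold change was 0.109. At an unadjusted threshold 1908 genes passed. Histone and other shared probe sets were read from a fit over all probe sets. In simulated data with the same groups, with 200 of 4476 genes changed, the test recovered 28.6% of changes of 0.5 on the log2 scale, 99.3% of changes of 1 and 100% of changes of 2, with false shares of 3.49%, 4.04% and 5.39% of calls. The simulated genes varied independently, with no effect shared by an array or culture, and fewer genes changed than were called in the data. These shares therefore do not bound the error of the calls reported here.

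Before the data were examined, 39 gene lists, the tests, most alternatives and the rule for named genes were fixed. Camera with a preset inter-gene correlation of 0.01 tested the 35 lists with at least 5 tested members, the outermost 10 tested genes of each chromosome arm by systematic name, and the 16 chromosomes. Camera with a preset correlation called 21 lists, 15 higher and 6 lower. With an estimated correlation it called 0, with adjusted p from 0.311 upward, and fry called 22. The form with an estimated correlation uses the 2 residual degrees of freedom, which leaves it little power. A list that fails it is not thereby shown to hold correlated genes. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. The named genes were the listed histone genes, the 12 genes with a standard symbol and the largest called change in each direction whose mutant arrays lay outside the wild-type arrays, up to 4 called members per list by moderated statistic (2 uncalled members where none was called), and the 5 largest called changes in each direction near chromosome ends. A name in a list was matched to the current symbol, and to a synonym only where no gene bears that symbol and 1 gene has that synonym. This synonym rule was corrected after the results had been seen, because an earlier form took synonyms of the wrong gene where the right gene was too dim (such as GRR1 for SDC1). The correction changed the members of some lists, and it brought the methionine and sulfur list, which had not passed before, under the threshold. Other genes named alone, such as ATO3, COS9, SST2 as a list member and the uncalled pheromone genes, were chosen after their values were seen.

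The alternatives changed 1 choice at a time, except that the lists with too few members past the filter were fitted with no filter together with a further change, added after the data were seen. They were an offset of 1 or 64, median centring, quantile normalization, no filter or a filter at the median, no intensity trend, a robust prior, the replicate number as a block, leaving out each array, other thresholds, other ways to handle probe sets, and other sizes of the chromosome-end set. A fit without the stretch of disagreeing probe sets and a scaling to the hybridization controls were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.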

Results

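Transcript levels were measured in budding yeast (Saccharomyces cerevisiae) whose histone H3 carried glycine in place of 8 lysines, at positions 4, 9, 14, 18, 23, 27, 36 and 79, and in a wild-type strain. Lysine 79 lies in the globular core of H3 and the others in its tail, where several are known sites of acetylation or methylation in yeast. Each group had 2 one-colour arrays (n = 2) of total RNA from cells in mid-log growth in rich medium, and each array gave a signal for 9335 probe sets. The number of arrays limits the precision, and no read depth applies. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these 4 arrays. Across the 4476 tested genes the log2 signals of the 2 wild-type arrays correlated at r = 0.991 and those of the 2 mutant arrays at r = 0.989, against 0.942 to 0.949 between groups. These correlations are across genes, which are not independent replicates. The question was which transcripts differ in the strain with these H3 lysines replaced together. The labels do not give the mating type, ploidy or other genotype of the strains. Any other difference between the strains would bear on every result below and cannot be told apart from the H3 change.

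Among tested genes the largest losses in the mutant were of transcripts that mark the a mating type and haploid cells. The pheromone gene MFA2 fell from a signal of 1168 ± 127 (SD, n = 2) to 33.6 ± 0.354 (SD, n = 2), and the pheromone receptor gene STE2 fell from 215 ± 18.7 to 8.0 ± 0.990 (SD, n = 2 each). The largest gains of tested genes outside ribosomal RNA included SNZ1, a vitamin B6 synthesis gene, from 63.0 ± 0.636 to 722 ± 29.6. They also included the zinc transporter gene ZRT1, from 120.0 ± 13.2 to 879 ± 4.31, and SGA1, from 34.35 ± 5.16 to 262 ± 4.74. The flocculin gene FLO11 rose from 67.2 ± 5.87 to 399 ± 14.3 (SD, n = 2 each). Of 4476 genes tested, 641 rose and 694 fell, and 93 and 41 of these changed at least 2-fold. Fold changes here are on the log2(signal + 16) scale, which understates the change of dim genes. In all 1335 called genes both mutant arrays lay on the same side of both wild-type arrays. Such separation held for 3019 of the tested genes (67.4%), where chance gives 33.3%. All changes are relative to arrays scaled to a common trimmed mean. The hybridization controls added to each sample were brighter on the mutant arrays, with geometric means of 138 and 141 in wild type and 174 and 201 in the mutant. Scaling to them moved the median log2 fold change of all genes from -0.03 to -0.39 and the share of calls that were higher from 48.0% to 7.61%. The balance of gains and losses therefore rests on the scaling. With 1 array left out, the number of called genes lay between 771 (without mutant replicate 1) and 914 (without wild-type replicate 2), with 795 without wild-type replicate 1 and 833 without mutant replicate 2.

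All 6 tested a-specific genes fell in the mutant, and so did most tested haploid-specific genes. Both genes for the a-factor pheromone fell, MFA2 with a log2 fold change of -4.57 ± 0.102 (SE) and MFA1 with -3.88 ± 0.128 (465 ± 84.0 to 16.5 ± 0.566, SD, n = 2 each). BAR1, the protease that degrades alpha factor, fell from 283 ± 34.9 to 21.2 ± 0.849, and STE6, the a-factor exporter, fell from 213 ± 65.8 to 23.0 ± 3.82 (SD, n = 2 each). The adjusted p was 2.93e-08 for MFA2 and 2.14e-05 for STE6. The median of the a-specific list was -3.13, and 0 members rose and 6 fell over all genes tested and also adjusted over the list alone. The list had a camera adjusted p of 3.00e-09, and an adjusted p = 0.311 with an estimated correlation.

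Of 15 tested haploid-specific and pheromone response genes, 9 fell, 2 rose and 4 did not pass, with the same counts of 9 and 2 adjusted over the list alone. FAR1, which arrests the cell cycle in response to pheromone, fell by 2.88 on the log2 scale, and the pheromone-pathway kinase gene FUS3 fell from 119 ± 8.20 to 5.80 ± 1.41 (SD, n = 2 each). HO, the endonuclease of mating-type switching, fell from 107 ± 10.9 to 10.3 ± 0.212, and RME1, a repressor of meiosis, fell from 192 ± 5.73 to 32.4 ± 4.60. The genes for the G protein subunits coupled to the pheromone receptor, GPA1 and STE4, fell by 1.83 and 1.95 on the log2 scale. SST2, STE5 and STE12 fell as well, while FIG2 and PRM1, both known as pheromone-induced genes, rose. AGA1, PRM4, PRM5 and MSG5 did not pass, with log2 values of 0.02, -0.24, -0.22 and -0.08. The median of the list was -0.97 (-0.29 with no filter on signal and -1.95 with a filter at the median), with a camera adjusted p of 1.19e-05 and an adjusted p = 0.311 with an estimated correlation.

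**Figure D1:**
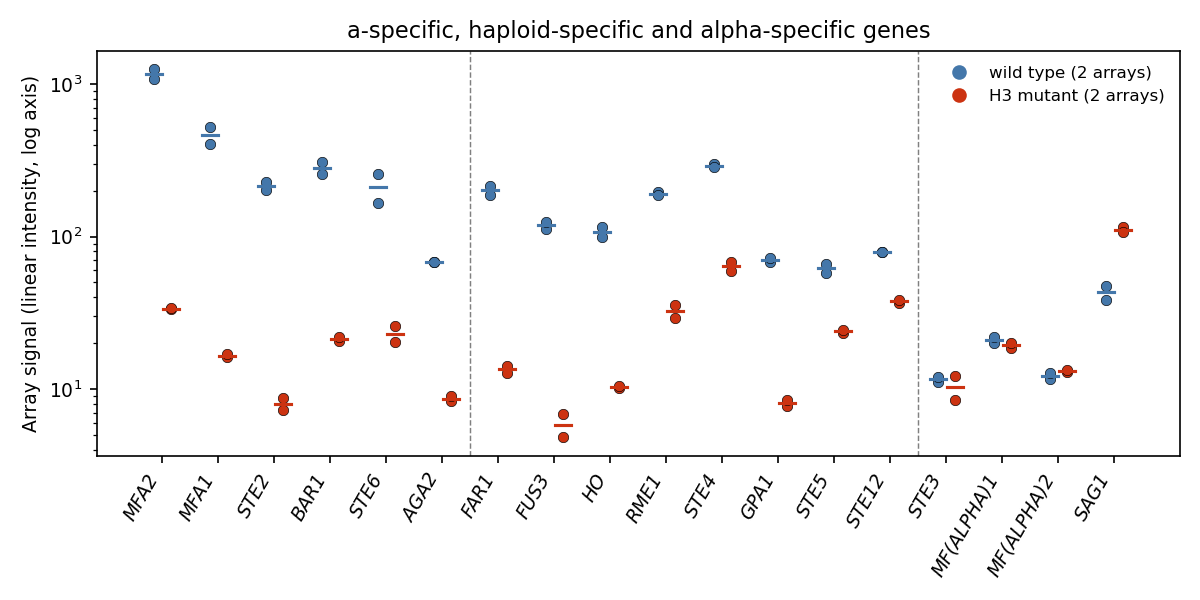
Signal (linear intensity, log axis) of a-specific, haploid-specific and alpha-specific genes on each wild-type and mutant array. MFA2 averaged 1168 in wild type and 33.6 in the mutant, while the alpha-specific STE3 averaged 11.5 and 10.2, below the limit for testing.

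The genes that mark alpha cells stayed near the floor in both strains, apart from SAG1. SAG1, the alpha-agglutinin gene, was the 1 tested member of its list and rose from 43.0 ± 6.29 to 111 ± 6.43 (SD, n = 2 each), a log2 fold change of 1.11 with an adjusted p of 0.000212. The alpha-factor receptor gene STE3 gave 11.5 ± 0.636 and 10.2 ± 2.62, and the alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 gave 20.9 against 19.4 and 12.2 against 13.2, below the limit for testing (signal 25.1). Probe sets paired with MATALPHA2, HMLALPHA2 and HMRA2 together gave log2 changes of 0.72 (adjusted p = 0.0867 over all probe sets) and -0.28 (adjusted p = 0.371). Because HMRA2 belongs to the a information, they do not single out the alpha gene. The brighter probe set of MATALPHA1 and its silent copy gave 0.41 (adjusted p = 0.160). On the a side, the brightest probe set of HMRA1, an a1 gene, gave 94.05 in wild type and 73.35 in the mutant. Its log2 change was -0.30 (adjusted p = 0.0894 over all probe sets), and dimmer HMRA1 probe sets gave -0.17 and 0.05. Few meiosis and sporulation genes were bright enough to test. With no filter on signal, 6 of 21 early meiosis genes and 11 of 25 middle and late sporulation genes rose, 0 and 1 fell, and the list medians were 0.19 and 0.19 (camera adjusted p = 0.00333 and 0.000539, adjusted p = 0.303 for each with an estimated correlation). Under scaling to the hybridization controls 6 and 3 rose, with medians of 0.0527 and 0.0964, and with 1 array left out 1 to 6 and 2 to 7 rose, the fewest without wild-type replicate 1 and wild-type replicate 2. Most of these genes have signals near the floor. SPS19, a peroxisomal enzyme gene induced in sporulation, rose from 45.7 ± 2.69 to 175 ± 4.60 (SD, n = 2 each). The brightest probe set of the sporulation gene CDA2 fell from 65.5 ± 1.34 to 41.9 ± 5.44 (SD, n = 2 each), and SPR6 gave 108 and 110.0. That CDA2 probe set is of a type that can cross-hybridise. Other CDA2 probe sets were near the floor, at 2.1 against 1.2 and 1.4 against 2.2, so a fall of CDA2 itself is uncertain. The CDA2 call was lost in 3 of the 4 fits that left out 1 array, with an adjusted p of up to 0.0939. RED1 and IME1, early meiosis genes, gave log2 changes of 0.35 and 0.23 and did not pass.

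The probe sets for histone H3 itself did not move together. Because 3 probe sets are each paired with both H3 genes, HHT1 and HHT2, none can be assigned to a single gene. The first fell from 680 ± 56.7 to 75.4 ± 0.283 (log2 fold change -2.93, adjusted p = 0.000254 over all probe sets). The second gave 3235 ± 490 and 4142 ± 74.4 (0.36, adjusted p = 0.150), and the third was at 2.25 in both groups (SD, n = 2 each). Replacing codons need not change an mRNA level, so these values do not check the labels. The platform's table does not say which gene copy or part of the transcript each probe set reads. By number, the first lies between probe sets of HTB2 and FUS3 on chromosome II. The second lies between those of CIT1 and MFA2 on chromosome XIV. They may therefore stand for different H3 copies, which was not tested. The fall of the first need not be a fall of H3 mRNA. The probe set shared by the H4 genes HHF1 and HHF2 gave 0.19 (adjusted p = 0.264). Those shared by the H2A genes HTA1 and HTA2 gave -0.74 (adjusted p = 0.0108) and -0.20 (adjusted p = 0.215). Of the 5 histone genes tested alone, which include the linker histone gene HHO1 and the variant genes HTZ1 and CSE4, 0 rose, 1 fell and 4 did not pass, and 0 passed when adjusted over the list alone. The list's camera adjusted p was 0.639. HTB1, an H2B gene, fell from 877 ± 61.0 to 709 ± 5.16 with an adjusted p of 0.0440, a call lost whichever array was left out (adjusted p from 0.0538 to 0.176). HTB2, HHO1, HTZ1 and CSE4 gave -0.08, -0.20, 0.09 and 0.07.

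Many genes of respiration and of growth on carbon sources other than glucose were raised in the mutant, although the cells grew in glucose-rich medium. MAL11, a maltose transporter gene, rose from 35.0 ± 3.11 to 132 ± 0.636, and ALD4, the mitochondrial acetaldehyde dehydrogenase gene, rose from 291 ± 38 to 716 ± 9.62 (SD, n = 2 each). JEN1, a lactate transporter gene, and PCK1, the first enzyme of gluconeogenesis, rose by 1.05 and 1.03 on the log2 scale. Of 17 tested glucose-repressed genes 13 rose, 1 fell (ATO3) and 3 did not pass, with 13 and 1 adjusted over the list alone and a median of 0.65 (camera adjusted p = 2.16e-06). The list had an adjusted p = 0.311 with an estimated correlation, and under scaling to the hybridization controls its median was 0.33. Of 15 tested genes of the tricarboxylic acid cycle 12 rose and 3 did not pass, with 12 higher and 1 lower adjusted over the list alone. ACO1, the aconitase gene, rose from 694 ± 69.2 to 1282 ± 51.7, and CIT1, a citrate synthase gene, rose from 640.5 ± 21.1 to 1042 ± 56.1 (SD, n = 2 each). The succinate dehydrogenase gene SDH2 and the succinyl-CoA ligase gene LSC2 rose by 0.78 and 0.59. This list had a median of 0.48 and a camera adjusted p of 9.70e-05, with an adjusted p = 0.319 with an estimated correlation, and under scaling to the hybridization controls its median was 0.0663 (camera adjusted p = 0.00573). CIT2, the peroxisomal citrate synthase gene, rose from 79.6 ± 0.566 to 296 ± 62.9.

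The medians of oxidative phosphorylation, glycolysis and hexose transport genes were above 0 but turned negative under scaling to the hybridization controls. Of 31 oxidative phosphorylation genes 6 rose, 1 fell and 24 did not pass (5 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.00725, adjusted p = 0.508 with an estimated correlation) that became -0.25 under that scaling and 0.0867 without mutant replicate 1. This list was not called with the replicate number as a block (camera adjusted p = 0.0937). The complex III gene QCR2 rose from 499 ± 25.8 to 699.8 ± 11.2 (SD, n = 2 each). ATP3, of the ATP synthase, rose by 0.38 but gave -0.03 with that scaling, and its call was lost in 3 of the 4 fits without 1 array (adjusted p up to 0.106). Of 16 glycolysis and fermentation genes 3 rose, 1 fell and 12 did not pass, with the same 3 and 1 adjusted over the list alone. The pyruvate decarboxylase gene PDC5 rose from 203 ± 1.06 to 350.5 ± 23.6 and the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 from 408 ± 21.8 to 649.5 ± 26.8, while the phosphofructokinase gene PFK2 fell from 1235 ± 6.29 to 963 ± 1.98, a call lost without any 1 array (adjusted p up to 0.122). The glycolysis median was 0.24 (camera adjusted p = 0.00799, adjusted p = 0.531 with an estimated correlation), and -0.17 under that scaling, and quantile normalization ended the call (median 0.0436, adjusted p = 0.260). Of 7 tested hexose transporter genes 4 rose, 1 fell and 2 did not pass (5 and 1 adjusted over the list alone). HXT5 rose from 12.4 ± 1.20 to 61.7 ± 2.76, and HXT1, a low-affinity transporter gene, fell from 542 ± 26.7 to 357 ± 22.6. The hexose transporter median was 0.37 (camera adjusted p = 0.0299, adjusted p = 0.319 with an estimated correlation), and -0.04 under that scaling. None of these lists was called by camera under that scaling (adjusted p = 0.341 for oxidative phosphorylation, 0.146 for glycolysis and 0.0750 for hexose transporters). The hexose transporter call was lost without wild-type replicate 1 (adjusted p = 0.0648), mutant replicate 1 (0.141) or mutant replicate 2 (0.257), that of glycolysis without wild-type replicate 1 (0.0739), and that of oxidative phosphorylation without mutant replicate 1 (0.0958).

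**Figure D2:**
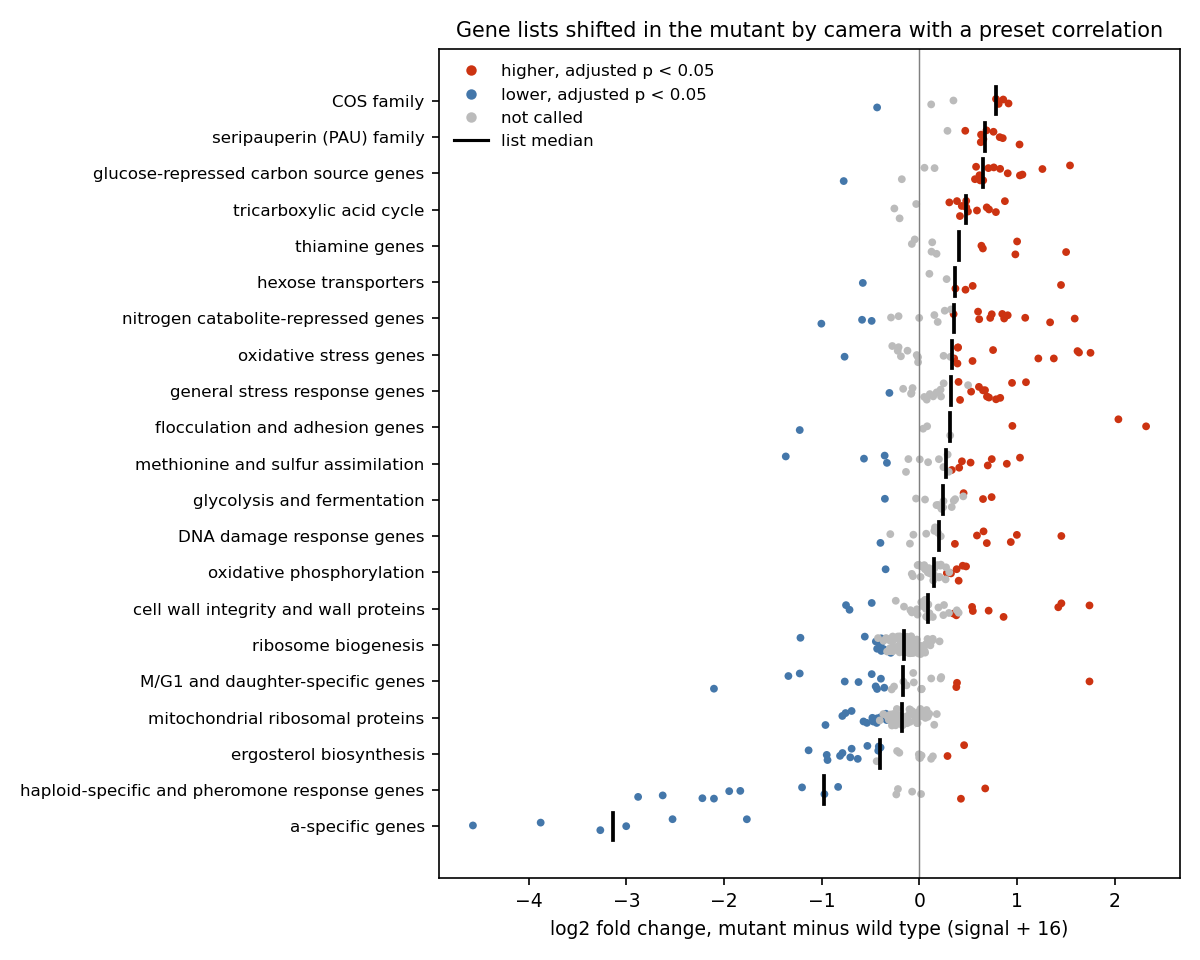
Log2 fold change, mutant minus wild type, of each tested gene (points) in the 21 lists that passed camera with a preset correlation, with the list median as a bar. Medians ran from -3.13 for a-specific genes to 0.78 for the COS family, 0 lists passed with an estimated correlation, and the medians of 9 lists above 0 turned negative under scaling to the hybridization controls, which lowers all genes, while camera called 16 of the 21 in the same direction and 0 in the opposite direction.

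Many stress-response genes were raised as well. GAD1, a glutamate decarboxylase gene, rose from 74.6 ± 1.56 to 177 ± 20.4, and HSP12, a membrane-protecting stress protein gene, rose from 411 ± 21.7 to 683 ± 18.7 (SD, n = 2 each). Of 26 general stress genes 12 rose, 1 fell (PNC1) and 13 did not pass (13 and 1 adjusted over the list alone), with a median of 0.32 that became -0.08 under scaling to the hybridization controls, where camera still called the list higher (adjusted p = 0.000938). The camera adjusted p was 0.000112, with an adjusted p = 0.319 with an estimated correlation. Of 22 oxidative stress genes 11 rose, 1 fell (GPX2) and 10 did not pass (13 and 3 adjusted over the list alone), with a median of 0.34 that became -0.03 under that scaling, where camera still called the list higher (adjusted p = 0.00238). OYE3, an NADPH oxidoreductase gene, rose from 47.7 ± 1.56 to 182 ± 9.55, SRX1, the sulfiredoxin gene, from 94.95 ± 11.7 to 324 ± 7.92, and the aryl-alcohol dehydrogenase family member AAD4 from 314 ± 13.4 to 1096 ± 64.1 (SD, n = 2 each). AAD probe sets can cross-hybridise within that family. The oxidative stress list had a camera adjusted p of 0.00236 and an adjusted p = 0.319 with an estimated correlation.

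Several DNA damage response genes were raised. The ribonucleotide reductase gene RNR3 rose from 22.2 ± 1.20 to 88.7 ± 2.62 and RNR4 from 759.5 ± 20.1 to 1234 ± 28.0 (SD, n = 2 each), and HUG1, a damage-induced inhibitor of ribonucleotide reductase, rose from 58.4 ± 8.56 to 132 ± 3.39. Of 16 tested members 7 rose, 1 fell (RAD23) and 8 did not pass (7 and 2 adjusted over the list alone), with a median of 0.20 that became -0.09 under scaling to the hybridization controls, where camera still called the list higher (adjusted p = 0.00502). Its call was lost with no filter (median 0.16, adjusted p = 0.0526) and with a filter at the median (0.11, adjusted p = 0.139), and its median was 0.36 without probe set numbers 5600 to 6699. The camera adjusted p was 0.00578, with an adjusted p = 0.319 with an estimated correlation. Of 35 cell wall genes 9 rose, 3 fell and 23 did not pass (11 and 3 adjusted over the list alone). PIR3, a wall glycoprotein gene, rose from 141 ± 16.3 to 508 ± 28.1, GSC2, a stress-induced glucan synthase gene, rose from 90.2 ± 7.0 to 275 ± 33.4, and UTR2, a chitin transglycosylase gene, fell from 841 ± 5.16 to 493 ± 0.212 (SD, n = 2 each). The wall list's median of 0.09 became -0.32 under that scaling, where it was not called (camera adjusted p = 0.0538), and was 0.15 without wild-type replicate 2 and 0.14 without mutant replicate 1. The list had a camera adjusted p of 0.00823 and an adjusted p = 0.319 with an estimated correlation. Its call was lost without wild-type replicate 1 (adjusted p = 0.0602).

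Some genes of nitrogen, thiamine and sulfur metabolism were also raised. DAL4 and DAL1, genes for uptake and breakdown of allantoin, rose from 12.2 ± 1.20 to 69.0 ± 1.63 and from 13.6 ± 0.212 to 58.7 ± 5.44, and the arginase gene CAR1 rose from 716 ± 36.3 to 1533 ± 35.8 (SD, n = 2 each). The amino acid permease gene DIP5 fell from 318 ± 17.1 to 151 ± 18.6. Of 21 nitrogen catabolite-repressed genes 11 rose, 3 fell and 7 did not pass (13 and 3 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00137, adjusted p = 0.319 with an estimated correlation). Their median was 0.0341 under scaling to the hybridization controls (camera adjusted p = 0.000313) and 0.60 without probe set numbers 5600 to 6699, and a filter at the median ended the call (median 0.19, adjusted p = 0.605). Of 10 thiamine genes 5 rose and 5 did not pass, with 5 adjusted over the list alone and a median of 0.40 (camera adjusted p = 0.00236, adjusted p = 0.319 with an estimated correlation) that was 0.0514 under that scaling (camera adjusted p = 0.000603) and 0.63 without those probe sets. THI7, the thiamine transporter gene, rose from 92.8 ± 3.32 to 292 ± 16.4 and THI4, of thiamine synthesis, from 49.3 ± 3.75 to 113 ± 9.48 (SD, n = 2 each). The vitamin B6 pair SNZ1 and SNO1 rose by 3.22 and 2.42. Of 20 methionine and sulfur genes 8 rose, 4 fell and 8 did not pass (10 and 4 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0339, adjusted p = 0.330 with an estimated correlation) that became -0.08 under scaling to the hybridization controls, where the list was not called (camera adjusted p = 0.215). MET1 and MET10, of sulfate assimilation, rose by 1.03 and 0.89, while SAM2, an S-adenosylmethionine synthetase gene, fell by 1.37. The sulfur list's call was lost without mutant replicate 1 (adjusted p = 0.107) or mutant replicate 2 (adjusted p = 0.0796), with a filter at the median (0.172) and with a replicate block (0.156).

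Of 24 ergosterol synthesis genes 12 fell, 2 rose (HMG2 and ERG1) and 10 did not pass (13 lower and 2 higher adjusted over the list alone). ERG5, a sterol desaturase gene, fell from 324 ± 14.7 to 139 ± 18.9, and HMG1, an HMG-CoA reductase gene, fell from 712 ± 34.6 to 363 ± 7.50 (SD, n = 2 each). ERG8 and ERG26 fell by 0.95 and 0.79. The list had a median of -0.41 (camera adjusted p = 0.00137, adjusted p = 0.319 with an estimated correlation), and -0.82 under scaling to the hybridization controls. Of 61 mitochondrial ribosomal protein genes 13 fell and 48 did not pass (11 lower adjusted over the list alone). MRPL38 fell from 146 ± 3.25 to 84.4 ± 7.42 and MRPL31 from 82.0 ± 11.2 to 40.5 ± 1.91 (SD, n = 2 each), with a list median of -0.18 (camera adjusted p = 0.00181, adjusted p = 0.319 with an estimated correlation) that was -0.52 under that scaling. Of 91 ribosome biogenesis genes 11 fell and 80 did not pass, and 1 fell adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00179, adjusted p = 0.500 with an estimated correlation) that was -0.52 under that scaling. DIP2, of the small-subunit processome, fell from 217 ± 19.0 to 142 ± 10.8, and HAS1, an RNA helicase gene, fell by 0.40, a call lost without wild-type replicate 2 or mutant replicate 2 (adjusted p up to 0.0858).

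Of 25 genes of the M/G1 transition and of daughter cells, 10 fell, 3 rose and 12 did not pass (12 lower and 3 higher adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.0462, adjusted p = 0.352 with an estimated correlation). AMN1, which acts in daughter-cell mitotic exit control, fell from 345 ± 23.1 to 127 ± 24, and TEC1, a filamentation transcription factor gene, fell from 164 ± 5.80 to 61.2 ± 8.20 (SD, n = 2 each). RME1 belongs to this list as well. The M/G1 call was lost without wild-type replicate 2 (adjusted p = 0.0748) or mutant replicate 1 (adjusted p = 0.0891), with median centring (0.0531), quantile normalization (0.0554) or a filter at the median (0.121), and the median was -0.58 under scaling to the hybridization controls. The flocculation and adhesion list had 7 tested members, of which 3 rose, 1 fell (TEC1) and 3 did not pass, with the same 3 and 1 adjusted over the list alone. FLO11 and FLO1, both cell-surface flocculin genes, rose by 2.32 and 2.04 on the log2 scale and FLO10 by 0.95. The median was 0.31 and became -0.00 under scaling to the hybridization controls, where camera still called the list higher (adjusted p = 0.000313), and was 0.18 without mutant replicate 1. The list had a camera adjusted p of 0.0276 and an adjusted p = 0.352 with an estimated correlation. This call was lost without wild-type replicate 2 (adjusted p = 0.0620). FLO probe sets can cross-hybridise within the family.

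Many genes near chromosome ends were raised in the mutant. The outermost 10 tested genes of each chromosome arm, 320 genes, had a mean log2 fold change of 0.23 against -0.02 for the other 4036 genes, a difference of 0.25. The medians were 0.0796 and -0.0334, so the mean rests on part of the set. In the set 103 genes rose (32.2%), against 521 (12.9%) outside it, with an odds ratio of 3.20 (95% confidence interval 2.46 to 4.14, 2-sided Fisher's exact p = 1.81e-17). Losses were 39 in the set and 627 outside it, with an odds ratio of 0.755 (0.520 to 1.07, 2-sided Fisher's exact p = 0.125). Fisher's test treats genes as independent. Camera gave p = 5.03e-05, and p = 0.114 with an estimated correlation. Fry, which tests for a net shift within the set with allowance for correlation among its genes and without comparison to other genes, gave p = 0.00890. The mean fell off with gene order, from 0.51 for the outermost 1 to 2 genes to 0.23 for ranks 3 to 5, 0.11 for ranks 6 to 10 and 0.02 for ranks 11 to 20. YAR068W, on chromosome I, rose from 11.8 ± 6.72 to 257 ± 17.6, and YNR064C, on chromosome XIV, from 10.5 ± 5.16 to 150.3 ± 20.7 (SD, n = 2 each). ZRT1, FLO1 and AAD4 belong to the set too. The lower genes with the largest change were the phosphate transporter gene PHO84, from 852 ± 34.1 to 181 ± 18.0, SST2 (-1.20), DIP5, YER186C (-0.75) and AIM20 (-0.73).

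**Figure D3:**
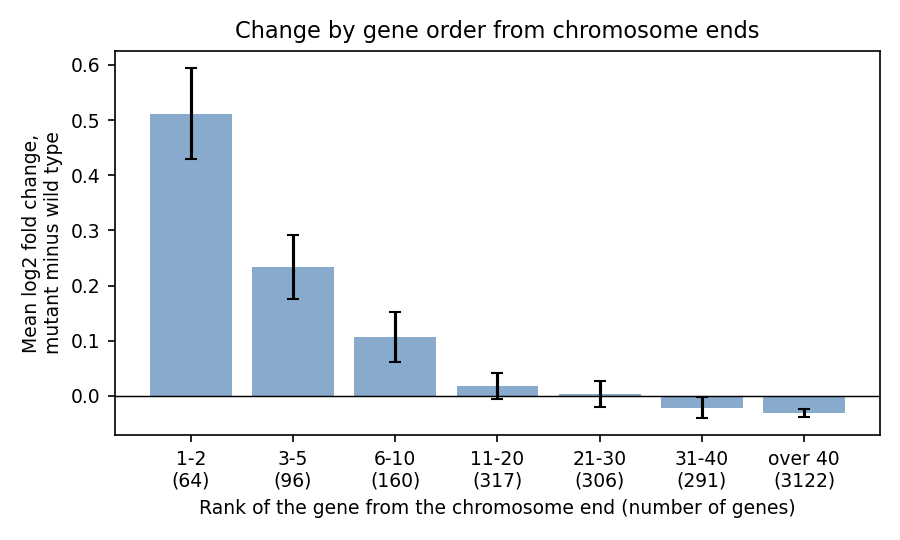
Mean log2 fold change, mutant minus wild type, by rank of the gene from the chromosome end, with the number of genes per bin. Bars are means and error bars the standard error over genes, and the mean is 0.51 for the outermost 1 to 2 genes and -0.03 for genes beyond rank 40.

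The gene families typical of chromosome ends followed. In the seripauperin (PAU) family, genes known for induction in anaerobic growth, 9 of 10 tested members rose and 1 did not pass, with 10 higher adjusted over the list alone. PAU23 rose from 163 ± 1.56 to 348 ± 24.7 and PAU17 from 53.0 ± 1.56 to 109 ± 3.82 (SD, n = 2 each), with a family median of 0.67 (camera adjusted p = 2.16e-06, adjusted p = 0.311 with an estimated correlation) that was 0.31 under scaling to the hybridization controls. In the COS family of subtelomeric membrane protein genes 4 of 7 rose, 1 fell (COS9) and 2 did not pass, with the same 4 and 1 adjusted over the list alone. COS4 rose from 369 ± 10.7 to 682 ± 32.2 and COS8 from 146 ± 27.4 to 286 ± 1.48, with a family median of 0.78 (camera adjusted p = 0.00729, adjusted p = 0.319 with an estimated correlation) that was 0.44 without mutant replicate 2 and 0.40 under that scaling. Probe sets of all 10 PAU members and of 5 COS members are of types that can cross-hybridise, so the assignment to single members is uncertain. No whole chromosome shifted. Camera called 0 of 16, with a lowest adjusted p of 0.533.

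Many other groups did not pass the list test. Of 15 H3 lysine-modifying enzyme genes 2 fell (SWD1 and SAS3) and 13 did not pass, with the same 2 adjusted over the list alone (camera adjusted p = 0.220). The SWD1 and SAS3 calls were lost in 3 of the 4 fits without 1 array each (adjusted p up to 0.0969 and 0.124). Of 16 silencing and telomere-binding factor genes SAS4, an acetyltransferase complex gene, rose from 23.4 ± 1.34 to 61.3 ± 8.84 and RAP1 and ABF1 fell, with the same calls adjusted over the list alone and a camera adjusted p of 0.626. The RAP1 call was lost without wild-type replicate 1 or mutant replicate 2 and that of ABF1 without wild-type replicate 1 (adjusted p up to 0.0847 and 0.0664). Of 12 phosphate genes 4 rose and 5 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.584), with the acid phosphatase gene PHO5 rising from 59.1 ± 1.48 to 229.7 ± 19.1 while PHO84 and VTC4 fell. Of 9 zinc genes ZRT1, ADH4 and ZPS1 rose and 4 fell (3 and 4 adjusted over the list alone). The zinc list's median (-0.15) and mean (0.20) differed in sign, and camera gave an adjusted p of 0.907 in the upward direction. The sign of this median varied with the setting. It was 0.0187 with no filter, 0.15 without wild-type replicate 1 and -0.12 without wild-type replicate 2. Of 20 iron genes 5 rose and 4 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.791), among them the ferric reductase gene FRE2 at 1.09 and the mitochondrial iron transporter gene MRS4 at -0.84.

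Heat shock chaperones (8 of 24 rose and 1 fell, 9 and 3 adjusted over the list alone) had a camera adjusted p of 0.0524, with SSA3 rising by 0.97 and HSP82 from 425 ± 15.8 to 834 ± 23.6 (SD, n = 2 each). They passed without wild-type replicate 2 (adjusted p = 0.0357) or mutant replicate 2 (0.0477). Amino acid biosynthesis genes (12 of 42 rose and 5 fell, 12 and 6 adjusted over the list alone) had 0.0566, with ARG4 and LYS1 rising by 1.28 and 1.02, and passed without wild-type replicate 2 (0.0153) or mutant replicate 2 (0.0297). Cytosolic ribosomal protein genes (5 of 81 fell, 2 adjusted over the list alone, adjusted p = 0.414) included RPL22B at -0.64, and passed as higher without wild-type replicate 2 (adjusted p = 0.01003). The lists of G1/S and G2/M genes did not pass. Of 34 G1/S genes 3 fell (1 adjusted over the list alone, adjusted p = 0.891), GIC2 with the largest change at -0.87. Of 30 G2/M genes 3 rose and 3 fell (1 and 3 adjusted over the list alone, adjusted p = 0.887). In the proteasome PUP2 alone of 32 genes fell (0 adjusted over the list alone, adjusted p = 0.887), a call lost whichever array was left out (adjusted p up to 0.183). Of 16 purine genes 3 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.760). The purine gene IMD4 rose by 0.39 but gave -0.02 under scaling to the hybridization controls, and its call was lost in 3 of the 4 fits without 1 array (adjusted p up to 0.204). Of 6 auxotrophic marker genes 3 rose and 1 fell, likewise adjusted over the list alone (adjusted p = 0.564). HIS3 rose from 202 ± 22.8 to 293 ± 29.3 and CAN1 fell by 0.49. The HIS3 call was lost without wild-type replicate 1 or mutant replicate 1 (adjusted p up to 0.0727). Galactose genes were too dim for a list test, and GAL80, a repressor gene, fell by 0.34, a call lost in 3 of the 4 fits without 1 array (adjusted p up to 0.274).

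Ribosomal RNA gave the largest gain of a tested gene, but its probe sets differed widely. The RDN25-1 probe set tested rose from 372 ± 348 to 3945 ± 2.76 (SD, n = 2 each), a log2 fold change of 3.72 that lost its call with a robust variance prior (adjusted p = 0.131). The wild-type arrays gave 126 and 618, so the size of this gain and its rank depend on the wild-type array used. A second RDN25-1 probe set gave 13.4 ± 5.44 and 16.1 ± 4.45. Of the probe sets paired with RDN37-1, the precursor transcript, 1 gave 85.9 and 1509 and the brightest in wild type gave 1191 and 1313. The RDN5-1 probe sets, for 5S rRNA, gave log2 changes of 1.39 and 1.21 (adjusted p = 0.00286 and 0.00441 over all probe sets), while a probe set of RDN5-3, another 5S rRNA gene, gave 0.15 (adjusted p = 0.459).

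The mutant arrays disagreed most over a long stretch of probe set numbers. In numbers 5600 to 6699, which hold 514 of the 545 tested chromosome IV genes, the SD of the log2 difference between the mutant arrays was 0.351, against 0.164 elsewhere. For the wild-type pair the values were 0.168 and 0.191. Of 19 genes whose mutant arrays differed by more than 2-fold, 18 lay in the stretch, and 17 of these were lower in mutant replicate 2. Of the genes named by the fixed rule, MFA1, HTB1, SAS4, GPP2, HXT6, ATP16, UTR2, SER3, SAM2, IZH1, GIC2, CLB3, MCM3, ADE8 and CAN1 lie in it. Genes named outside that rule, such as SPR6, can lie in it as well. A shorter stretch, numbers 3200 to 3699 with 58 tested genes, among them COS4, also had a higher SD for the mutant pair (0.286 to 0.373 over blocks of 100) than for the wild-type pair (0.142 to 0.190). Without the long stretch, and with the shorter one kept, 1277 genes were called, 617 higher and 660 lower.

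**Figure D4:**
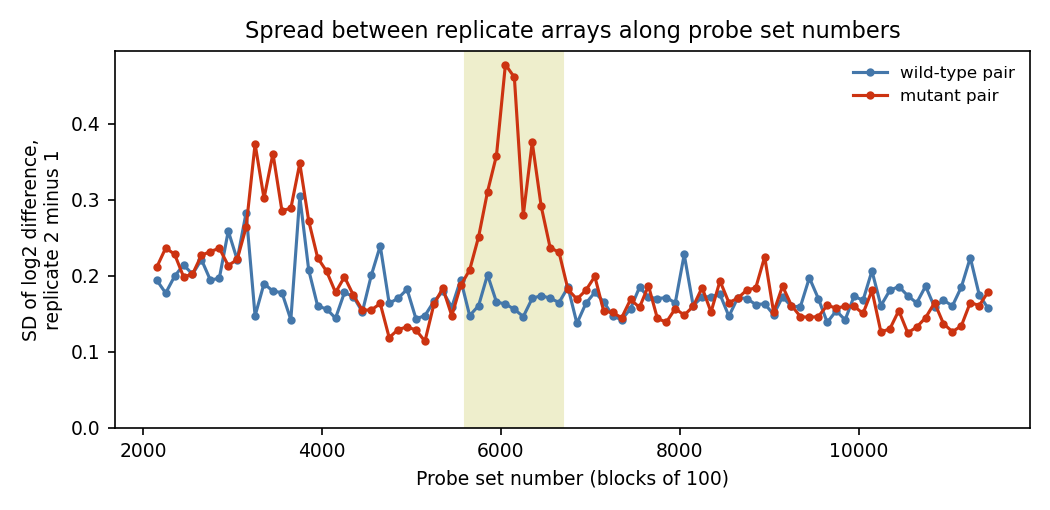
SD of the log2 difference between replicate arrays in blocks of 100 probe set numbers, for the wild-type pair and the mutant pair, with the stretch 5600 to 6699 shaded. In the stretch the SD over tested genes was 0.351 for the mutant pair and 0.168 for the wild-type pair.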

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

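The tests of explanations in this part were chosen after the results they test had been seen. Of 897 bright probe sets that are paired with no gene or with several, and so stand outside the gene comparison, 114 were higher and 27 lower in the mutant by a limma fit over all probe sets. Among them 4 probe sets with no gene in the platform's table and adjacent numbers had log2 fold changes of 3.04, 3.46, 4.64 and 3.24, with wild-type signals between 0.3 and 2.2. The next probe set by number, also without a gene, gave 1.29. A probe set paired with both H3 genes, HHT1 and HHT2, gave -2.93 while another probe set of the same pair gave 0.36. A control probe set for 25S rRNA gave 3.23, with signals of 252 and 780 in wild type and 4143 and 4474 in the mutant.

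The loss of a-specific and haploid-specific transcripts held the largest losses among tested genes. A replacement of a cells by alpha cells would raise the alpha-specific genes and leave the haploid-specific genes in place. The mean log2 fold change of STE3, MF(ALPHA)1 and MF(ALPHA)2 was -0.0290, but these genes lay below the limit for testing. SAG1, the only alpha-specific gene tested, was not in that mean and rose by 1.11. The haploid-specific list had a median of -0.97, which such a replacement alone would not give. Lower pheromone signalling alone would leave HO and RME1, which pheromone does not induce, unchanged, but their mean was -2.16. Cells that express both a and alpha information repress genes through the a1-alpha2 complex, and 8 of 8 tested genes known for such repression fell, but all of them belong to the haploid-specific list whose fall prompted the test, so the count does not bear on this explanation. The labels give neither mating type nor ploidy of the strains. A state with both a and alpha information may therefore still account for the pattern and stays open, whether through the silent mating-type copies or a second MAT locus. The brightest probe set of HMRA1, an a1 gene, gave 94.05 in wild type and 73.35 in the mutant, but is of a type that can cross-hybridise. The rise of SAG1, an alpha-specific gene, has no place in such a state.

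The rise of genes near chromosome ends was weighed against explanations from the measurement. A general rise of dim genes was set against 10000 random sets matched for signal, whose mean the set exceeded by 0.25, with 0 random sets as high. Without cross-hybridising probe sets and gene families the difference between the set and other genes was 0.19 (camera with a preset correlation, p = 0.00261), and without the 15 lists that rose it was 0.20 (p = 0.00190). A loss of repression near chromosome ends may therefore underlie it, which remains a hypothesis. The test of the set was fixed before the data were examined, while these checks were chosen after its result was seen. Camera gave p = 0.114 with an estimated correlation, which was 0.0267 for the set. That form of camera rests on the 2 residual degrees of freedom and has little power here. It therefore cannot decide whether the genes move as more than a correlated group, which stays open.

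The disagreement of the mutant arrays along the probe set numbers may come from a local defect on 1 array. The absolute difference between the mutant arrays had a highest autocorrelation along the numbers of 0.181, at a step of 69. The wild-type pair gave 0.0543 at most over the same steps of 50 to 150. A long stretch of larger spread raises this value at every such step by itself. The value therefore cannot show a repeat and does not bear on a local defect. A change in copy number of chromosome IV in 1 mutant culture would shift its genes one way, but the median difference of the 514 chromosome IV genes in the stretch was -0.00202. The scanned images were not used here, and no biological explanation was tested further. A smaller stretch, numbers 3200 to 3699, also had a higher SD in the mutant pair.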

How the results depend on the processing

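The fit without the long disagreeing stretch, the scaling to hybridization controls, and the further fits of meiosis and sporulation lists with no filter were chosen after the data were seen, and the other alternatives were planned. In each alternative fit 0 genes called in the report were called in the opposite direction. Among gene list values 479 stayed on their side of the threshold, 22 kept their sign but no longer passed, and 9 passed anew. The medians of called lists changed sign in 9, whether or not the call was kept. Among named genes and probe sets 2077 stayed, 116 kept their sign but no longer passed, and 5 passed anew. Called values changed sign in 3, again with or without the call. Some uncalled values among those that stayed changed sign too. The telomere-proximal difference stayed between 0.15 and 0.36 across all alternatives and passed in each except camera with an estimated correlation (difference 0.25, p = 0.114). With an estimated correlation 0 lists passed. That form of camera rests on the 2 residual degrees of freedom. The glucose-repressed and PAU lists lost their calls with estimated correlations of -0.0518 and -0.0503, below the preset 0.01. For these lists correlation among the genes does not account for the loss. The called H3 probe set (log2 fold change -2.93) kept its call in every fit that gave it a value. Other H3 probe sets were not called in the fit over all probe sets. The chromosomes gave 0 calls throughout.

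Scaling to the hybridization controls gave 2695 called genes, 205 higher and 2490 lower, and kept 897 of 1331 calls, since it lowers the mutant arrays relative to the wild-type arrays. By the same construction list medians became -0.0448 for hexose transporters, -0.17 for glycolysis, -0.25 for oxidative phosphorylation, -0.0810 for general stress, -0.0321 for oxidative stress, -0.32 for cell wall, -0.0788 for methionine, -0.0896 for DNA damage and -0.00204 for flocculation genes, while camera, which compares a list with other genes, called 16 of the 21 lists in the same direction and 0 in the opposite direction. The log2 fold change of ATP3 became -0.0323, the log2 fold change of CPR6 -0.0450 and the log2 fold change of IMD4 -0.0230. Stricter calling rules gave 640 genes at a threshold of 0.01, 134 with at least a 2-fold change, and 90 with a 2-fold change in all 4 comparisons of arrays. A filter at the median tested fewer genes and gave 425 higher.

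The filter at the median ended the calls of hexose transporters (0.32), methionine (0.17), nitrogen (0.19), M/G1 (-0.21) and DNA damage genes (0.11), and amino acid genes passed (0.13). Median centring ended M/G1 (-0.20). Quantile normalization ended glycolysis (0.0436) and M/G1 (-0.12), and amino acid genes passed (0.0659). No filter ended DNA damage (0.16) and gave values to the lists of early meiosis (0.19) and of middle and late sporulation (0.19), which passed as higher, also under each scaling (medians of 0.0527 to 0.15 and 0.0964 to 0.16) and without each array, but not with an estimated correlation (adjusted p = 0.303 for each). Galactose genes, at 0.26 with no filter, did not pass (adjusted p = 0.0813) except without mutant replicate 1 (adjusted p = 0.0408). The haploid-specific median was -0.29 with no filter and -1.95 with the filter at the median, and it passed in both. Heat shock chaperones passed with an offset of 1 (0.17) and with no intensity trend (0.16). The cause was not tested. With the replicate number as a replicate block, 1766 genes were called, and oxidative phosphorylation (0.15) and methionine genes (0.27) no longer passed. The same-numbered deviations of the 2 pairs correlated at 0.13 across genes, and the labels do not pair the arrays.

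Leaving out 1 array left a group with 1 array, assumed to vary like the other group, and gave 771 to 914 called genes, 390 to 481 higher and 314 to 458 lower. The fewest higher came without mutant replicate 1 and the fewest lower without wild-type replicate 1. List medians whose call changed ran from 0.32 to 0.39 for hexose transporters, 0.17 to 0.35 for glycolysis, 0.0867 to 0.20 for oxidative phosphorylation, 0.0121 to 0.12 for cytosolic ribosomal proteins, 0.0318 to 0.21 for heat shock chaperones, 0.0895 to 0.15 for cell wall genes, 0.0521 to 0.13 for amino acid genes, 0.22 to 0.29 for methionine genes, -0.22 to -0.17 for M/G1 genes and 0.18 to 0.45 for flocculation genes. Fewer samples lowered the power of these fits. Of 143 named called genes, 32 lost their call in at least 1 of them.

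Fewer than 5 members were left, and so no value, for hexose transporters and histones without the stretch, and for a-specific, flocculation, thiamine and histone genes with the filter at the median. The alternative that takes genes within 20 kb of a chromosome end was not run, since the coordinates of the array's build are not known. Genes with a signal near the offset have compressed changes, and those under the filter were not tested.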

Other observations

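The hypotheses of this re-analysis are weighed with the results singled out above, and the values here were looked at only after the data were seen. Among genes for transfer RNA, 24 of 69 fell and 0 rose in the mutant, with a median log2 fold change of -0.37, while under scaling to the hybridization controls 66 of 70 fell and the median was -0.68. The tRNA probe sets also differed within groups, with a median log2 difference of replicate 2 minus replicate 1 of 0.22 in the mutant and 0.30 in wild type, so the shift is close in size to the spread between replicates. Among small nucleolar RNA genes 9 of 38 rose and 3 fell, with a median of 0.0503, while under scaling to the hybridization controls 1 rose and 17 fell and the median was -0.30.

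All 4 tested genes encoded in the mitochondrial genome rose. COX1 and COX3, of cytochrome oxidase, rose by 0.50 and 0.82 on the log2 scale, COB, the cytochrome b gene, by 0.40, and OLI1, of the ATP synthase, by 0.36 but with -0.0579 under scaling to the hybridization controls. Their median of 0.45 became 0.11 under that scaling, with COX3 alone still called. The nuclear genes for mitochondrial ribosomal proteins had a median of -0.18.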
